A study of Mus musculus with 25 samples.

How the data were processed

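RNA-seq was measured in T cells of mouse spleen and lymph node on the C57BL/6 background. Treg are regulatory T cells, which depend on the transcription factor Foxp3, and Tconv are conventional T cells. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy mini or micro kit, libraries were made with an Illumina TruSeq RNA kit, and stimulated cells were kept for 3 h with 2 µg/ml of CD3 and CD28 antibodies plus IL-2. Groups were taken from the sample labels: 25 libraries fell into 14 groups, 21 of them in 10 groups of freshly isolated or stimulated cells and 4 in a separate set treated with TAT-Cre, a cell-permeable recombinase. p65 is the product of Rela and c-Rel that of Rel, and both are subunits of the transcription factor NF-kB. DKO stands for loss of both.

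The authors deposited gene-level FPKM values, fragments per kilobase of transcript per M mapped fragments, with lower and upper confidence bounds, in 1 file per library. Per the submitters' processing notes, bcl2fastq, TopHat and Cufflinks were used and the genome build was mm9; versions, the annotation and the strand setting are not given in the sources used here. Per the file headers the tables are Cufflinks gene tracking files, which hold estimates and no read counts. Each file had 23699 gene entries for 23235 symbols; 285 entries in each file were marked as having low data and 3 to 11 as failed, and the 250 symbols with any entry not marked as OK in some file were left out. FPKM values of the 181 kept symbols that stood on several entries were summed, which left 22985 symbols. A gene that overlaps another or has near-identical copies is uncertain here, because how Cufflinks divided its reads is not recorded in the files.

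No read totals are in the tables. The Cufflinks confidence bounds are set by an implied number of fragments per gene. Summed over the entries marked as OK, these gave a depth per library of 15.4 to 52.8 M fragments (M, 1e6). Of the implied numbers under 15, 70.5% to 74.4% per library lay within 0.02 of a whole number, so the depths are estimates. Library numbers in the labels form 4 consecutive runs: 1 to 2 (2 libraries, 18.7 to 22.6 M implied fragments), 6 to 7 (2 libraries, 18.3 to 21.2 M), 10 to 16 (7 libraries, 16.0 to 22.0 M) and 21 to 30 (10 libraries, 34.0 to 52.8 M). The TAT-Cre set, with numbers 31 to 34 that continue the last run, had 15.4 to 19.4 M. The labels do not call these runs batches. Correlations of deviations from the group means averaged 0.432 for 51 pairs of libraries in the same run (lowest 0.036) and -0.209 for pairs in different runs. Most groups with replicates had 2 libraries, of runs 3 and 4, whose deviations mirror each other. The negative value thus largely follows from the positive one, and only the same-run value bears on the runs. Each comparison's total of called genes is therefore given with the value from a fit that has the run as a block. Counts within gene lists are from the fit without a block unless said otherwise.

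Expression was analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a trend on mean expression, 1 mean per group over the 21 libraries outside the TAT-Cre set and 11 residual degrees of freedom. Genes with at least 1 FPKM in at least 2 libraries were tested, 11532 in all. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison are called. Fold changes are on this log2 scale, which understates changes of genes with low FPKM. Groups with 1 library (p65KO Treg stim and c-RelKO Treg stim) were tested with the spread of the other groups, assuming that the lone library varies as they do. Nothing in the labels says that replicates came from separate animals. Xist, expressed in females, was 59.3 to 131 FPKM in WT Treg replicates 1 to 3 and 0.0075 in replicate 4. In WT Tconv it was 47.4 and 0.0095, so replicates of these groups were not all from 1 animal. Both DKO Treg libraries had Xist (22.6 and 36.4), so there this stays open. The p-values measure only the spread between these samples, part of which may be technical.

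The groups, tests, covariates, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. The rule named Rela, Rel and Foxp3 in each comparison, the 12 largest rises and 12 largest falls among called genes with a group mean of at least 5 FPKM and no overlap between the libraries of the groups (no such condition for interactions), and up to 4 members of each gene list with the smallest p. Predicted genes, RIKEN clones, small RNAs and receptor segments were not named. The 23 gene lists held 373 symbols, of which 1 was not found: Treg signature, Tconv signature, Effector Treg, Resting or central T cell, NF-kB subunits, NF-kB feedback and target genes, TCR early response, Inflammatory cytokines, Interferon response, Cell cycle, Apoptosis regulators, TNF receptor superfamily, Chemokine receptors and homing, Glycolysis, Cholesterol synthesis, T cell identity, B cell markers, MHC class II, Myeloid markers, NK and CD8 T cell markers, Erythroid markers, Heat shock and dissociation stress, and Sex check. Some genes stand in several lists. Lists were tested with limma's camera, which asks whether the genes of a list move more than the other genes, with a preset correlation of 0.01 between genes and adjusted over the 23 lists of a comparison. Of 322 such tests 128 were called with the preset correlation and 13 with a correlation estimated from the data. List p-values below are the adjusted camera p with the preset correlation unless said otherwise.

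Programs defined within the data came from other libraries than those tested: the Treg program from WT Treg replicates 3 and 4 against WT Tconv, tested on replicates 1 and 2 as control, and the activation program from Tconv stimulated against resting. Overlaps between knockout comparisons that share the WT Treg controls were set beside 100 simulations of unchanged groups, beside the overlap of independent lists and beside 6 splits of the controls. The TAT-Cre libraries, 1 per group, were compared without a test over 10424 genes, and a list's median was placed among 10000 random lists of the same size matched on mean expression; the genes of stimulated DKO Treg were placed among random sets in the same way. The steps were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among the 11532. For p65KO Treg 71% and 96% of them were recovered, for DKO Treg 63% and 86%, for WT Treg stim 53% and 89%, and for p65KO Treg stim 28% and 81%. The changed genes were drawn only from those with a mean level of at least 5 FPKM in the group compared against. Recovery of lower genes was therefore not measured, and the simulated spread held no run effects.

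The alternatives were a pseudocount of 0.1, no filter, median-of-ratios size factors, a fit on the compared groups only, each library left out in turn, the replicate number as a block, the library run as a block, an estimated correlation for camera, a 1.5-fold threshold for the programs and other splits of the controls. Alternatives added after seeing the data were the fits without 3 libraries whose values raised doubts about label or purity (p65KO Treg replicate 3, p65KO Treg stim and c-RelKO Treg replicate 2), alone and with the run as a block, the naming of genes from the fit with the run as a block, and, for the overlaps, the run as a block and simulations with run effects. Replicate libraries of a group held no identical value above 0, and their correlations were 0.893 to 0.978. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading the files and for plots. Positions are 1-based mm9 coordinates from the deposited files.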

Results

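Expression was measured in 25 libraries of mouse T cells. Without stimulation there were 4 libraries of WT Treg, 3 of p65KO Treg, 2 of c-RelKO Treg, 2 of DKO Treg and 2 of WT Tconv. After 3 h with CD3 and CD28 antibodies and IL-2 there were 2 each of WT Treg, DKO Treg and WT Tconv, and 1 each of p65KO Treg and c-RelKO Treg. A separate set of 4 stimulated libraries was treated with TAT-Cre: WT Tconv control, WT Treg control, a Treg library labelled FoxP3-del and one labelled NFkB-del. Implied depth was 15.4 to 52.8 M fragments per library. Values are FPKM (mean ± SD) or log2 differences (± SE), and n is the number of libraries.

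The targeted genes were looked at first in every library. Rel (chr11:23641729-23670970) was nearly absent without c-Rel: 2.09 and 1.76 FPKM in c-RelKO Treg, 1.91 after stimulation, 2.06 and 1.96 in DKO Treg and 2.23 and 2.14 after stimulation. In WT Treg it was 27.5, 200, 271 and 252 FPKM, and 298 and 283 after stimulation. Rela (chr19:5637490-5648130) kept much of its transcript without p65. It was 58, 69.3 and 79.8 FPKM in p65KO Treg, 74.1 after stimulation, 76.1 and 56.3 in DKO Treg and 107 and 99 in stimulated DKO Treg, against 64.9, 99.1, 130 and 124 in WT Treg and 126 and 118 after stimulation. The 3 p65KO libraries lay below the WT library of their own run in each case (58 vs 64.9, 69.3 vs 99.1 and 79.8 vs 124). c-RelKO Treg had 133 and 137 FPKM of Rela, and 135 after stimulation. Gene-level FPKM covers all exons, and which exons were deleted is not given in the sources used here.

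**Figure D1:**
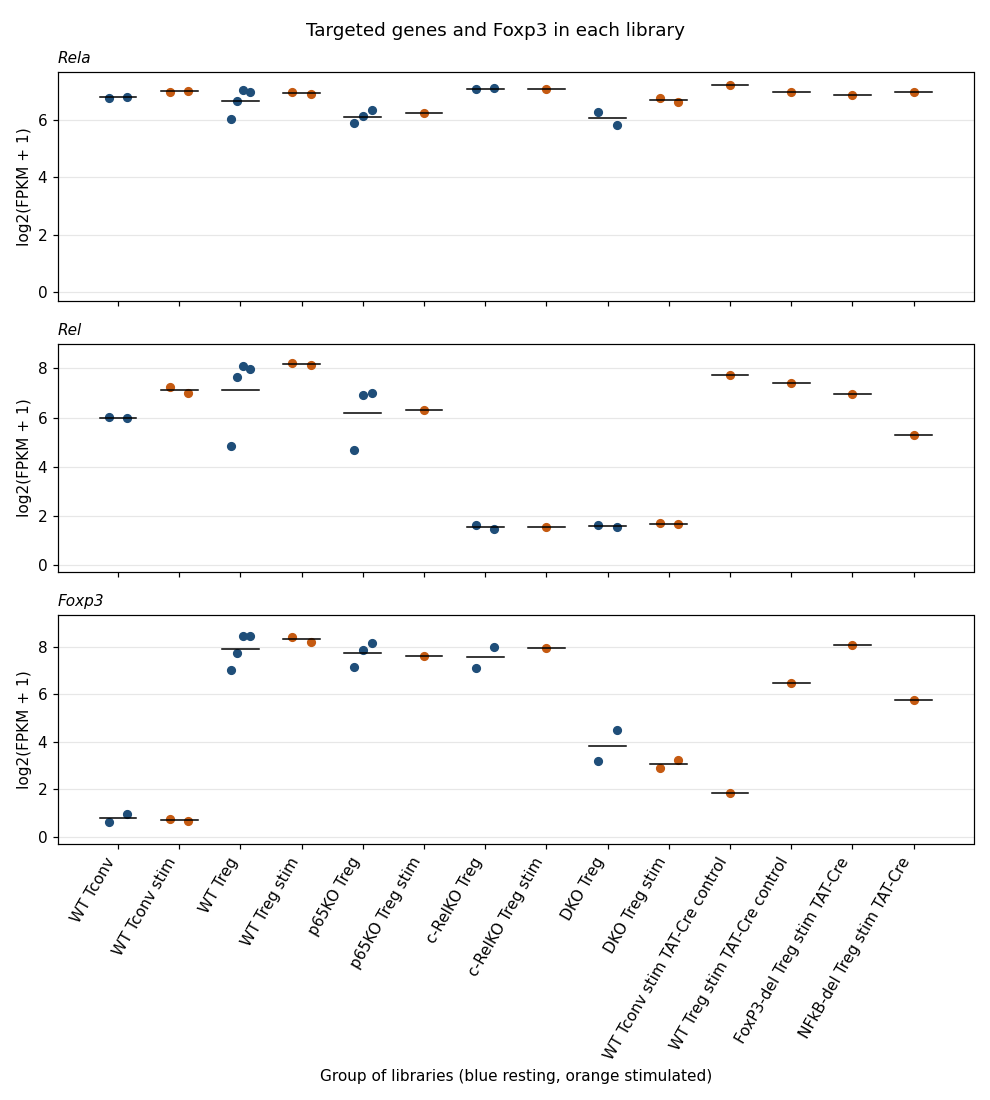
Rela, Rel and Foxp3 in each library as log2(FPKM + 1). Dots are libraries, lines are group means, blue is unstimulated and orange is stimulated.

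Foxp3 (chrX:7156802-7172369), the defining transcription factor of Treg, was 0.542 and 0.927 FPKM in WT Tconv and 129 to 351 in WT Treg. p65KO Treg had 140, 232 and 282 FPKM, against 129, 210 and 351 in the WT Treg libraries of the same runs. c-RelKO Treg was below WT Treg of its run each time, with 136 against 344 and 254 against 351 FPKM, and 245 against 295 after stimulation. In DKO Treg it was 8.01 and 21.2 FPKM, and 6.34 and 8.31 after stimulation, where WT Treg had 336 and 295. In the TAT-Cre set Foxp3 was 2.55 FPKM in the Tconv control, 86.7 in the Treg control, 53.4 in the library labelled NFkB-del and 266 in the library labelled FoxP3-del. Rel was 38.7 FPKM in the library labelled NFkB-del against 171 in the Treg control, and Rela was 124 against 125. Which gene the label NFkB-del refers to cannot be read from these values, although Rel was lower and Rela was not. Rela kept much of its transcript in p65KO Treg. Rel was also lower in p65KO Treg than in WT Treg of the same run (24.6 against 27.5, 120 against 200 and 128 against 252 FPKM). Because Foxp3 was higher where its label says deleted, this library is named by its label throughout and no direction is drawn from that label.

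WT Treg differed from WT Tconv first of all by Foxp3, which was 7.12 ± 0.43 higher in Treg (adjusted p = 5.7e-07, n = 4 and 2). Lrrc32, a surface protein that binds latent TGF-beta (chr7:105642732-105650340), was 6.38 ± 0.72 higher (461 ± 270 against 3.33 ± 0.0373 FPKM). Il2ra, a chain of the IL-2 receptor, was 4.48 ± 0.43 higher and the transcription factor Ikzf2 (chr1:69577784-69732534) 3.93 ± 0.17 higher. The G protein-coupled receptor Gpr83 was 5.65 ± 0.57 higher, and Coro2a, an actin-binding protein, 4.33 ± 0.39 higher. Lower in Treg were Il7r, the receptor for IL-7 (-3.28 ± 0.45), the phosphodiesterase Pde3b (-4.16 ± 0.28), Fam101b (-4.51 ± 0.58), Vipr1 (-3.85 ± 0.41) and Hs3st3b1 (-3.44 ± 0.19). Of the 35 Treg signature genes 34 were higher and none was lower, with a median of 3.28 (list adjusted p = 4.5e-31, and adjusted p = 0.00033 with an estimated correlation).

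Of 15 Tconv signature genes 8 were lower in Treg (9 adjusted over the list alone), among them Pde3b, Lef1 (-2.09) and Il7r (list adjusted p = 5.7e-07). Effector Treg genes were also higher, 20 of 29 (23 adjusted over the list alone), with Maf at 2.42, Ebi3 at 2.84, Gzmb at 3.44 and Itgae at 4.04 (list adjusted p = 6.5e-14). Cell cycle genes were higher in 10 of 24 cases, for example Rrm2 (1.89) and Top2a (1.79), with a list adjusted p of 1.2e-06, and adjusted p = 0.448 with an estimated correlation. Chemokine receptors and homing genes were higher in 10 of 24 cases and lower in 1, with Ccr6 at 3.54 and Ccr4 at 2.61 (list adjusted p = 0.00091, and adjusted p = 0.106 with an estimated correlation). In all 1449 genes were called, 811 higher and 638 lower in Treg. The larger side turned with the run as a block (2247 higher and 3040 lower, 5287 in all) and without WT Treg replicate 1 (1014 and 1297, 2311 in all). The count was 362 and 408 without Tconv replicate 2 or 1.

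Resting p65KO Treg had more Gzmb, the cytotoxic granule protease granzyme B (chr14:56877695-56881097), at 123 ± 28.6 against 22.1 ± 8.15 FPKM in WT Treg (2.46 ± 0.39, adjusted p = 0.045, n = 3 and 4). Lsr, a lipoprotein receptor (chr7:31742789-31758488), rose by 1.28 ± 0.18 (adjusted p = 0.0435) and Clcf1, a cytokine of the IL-6 family (chr19:4214392-4222615), fell by 0.73 ± 0.11 (adjusted p = 0.0435). The remaining called genes, Frmd5 (0.87) and Gm4951 (1.74), lie outside the rule for named genes and were chosen after their values were seen. Tbx21, the transcription factor T-bet, was 1.54 higher with an adjusted p of 0.0684. Foxp3 was not called (-0.20 ± 0.38, adjusted p = 0.908), nor was Rel (-0.93 ± 0.68, adjusted p = 0.707).

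Several gene lists were called in p65KO Treg although few of their genes were in the fit without a block, to which the counts in this paragraph belong. Within runs 1, 2 and 4 the mean log2 level of Cell cycle genes was 5.357, 4.557 and 4.699 in p65KO Treg. WT Treg of the same runs had 4.351, 4.131 and 3.95. Of 29 Effector Treg genes 1 was called over all genes and 11 adjusted over the list alone, all higher, with a median of 0.56 (list adjusted p = 3.0e-06, and adjusted p = 0.064 with an estimated correlation); Prdm1 was at 0.95 and Id2 at 0.78. Cell cycle genes lay higher by a median of 1.08, with 0 of 24 called over all genes and 23 adjusted over the list alone (list adjusted p = 5.3e-16, and adjusted p = 0.174 with an estimated correlation). NF-kB feedback and target genes lay lower by a median of -0.30, led by the adhesion molecule Icam1 (-1.16) and the inhibitor Nfkbia (-1.03), with 0 of 23 called and 2 adjusted over the list alone (list adjusted p = 3.8e-06, and adjusted p = 0.111 with an estimated correlation). The 5 NF-kB subunits lay lower by a median of -0.59, with Relb at -1.09 and 0 called (list adjusted p = 4.0e-05, and adjusted p = 0.18 with an estimated correlation). Heat shock and dissociation stress genes lay lower by a median of -0.23, none of 10 called (list adjusted p = 0.0016, and adjusted p = 0.507 with an estimated correlation). Markers of other cells differed within runs as well. In p65KO Treg the mean log2 level of B cell markers was 1.405, 0.961 and 0.409, against 2.439, 0.835 and 0.49 in WT Treg of the same runs. Myeloid markers were at 1.773, 2.016 and 3.18 against 2.849, 1.211 and 1.155.

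Only 5 genes were called by limma for p65KO Treg, 4 higher and 1 lower, although 1130 had an unadjusted p under 0.05. With the run as a block 1017 were called, without 3 libraries of doubtful label or purity 0, and with size factors, which take out a scale difference of 0.101, 0. Leaving out single libraries gave 0 to 21, with 21 without WT Treg replicate 2. Genes named from the fit with the run as a block were chosen after the data were seen: Gzmb (2.36) and the galectin Lgals3 (1.59) rose and the heat shock gene Hspa1b (-1.73) fell, and they stayed called at 2.31, 1.39 and -2.57 when the doubtful libraries were left out of that block fit (adjusted p = 0.0305, 0.0349 and 0.0078, 119 genes called, 2 p65KO libraries left). The chemokine Ccl4 (2.80), Tbx21 (1.56), Eps8l1 (-2.40), the costimulatory protein Cd83 (-1.12), Icam1 (-1.09) and Actn1 (-1.04) were not called there but stayed on the same side, at 2.42, 1.16, -1.93, -1.10, -0.68 and -0.72 (adjusted p = 0.154, 0.0884, 0.144, 0.055, 0.124 and 0.095). Cd83 was below WT Treg in each run, with 29.5 against 64.4, 142 against 307 and 122 against 276 FPKM.

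Treg without c-Rel lost Rel transcript (-5.59 ± 0.77, adjusted p = 0.00055, n = 2 and 4) and gained cytokine transcripts. Il22 (chr10:117642020-117647102) rose by 5.12 ± 0.60 to 51.6 ± 39.3 FPKM, the chemokine Xcl1 by 3.88 ± 0.98, Il13 by 3.19 ± 0.89 and Il4 by 3.15 ± 0.93. Natural killer receptors rose too, Klrc1 by 3.55 ± 0.65, Klrb1b by 3.29 ± 0.23 and Klrk1 by 3.05 ± 0.41, along with the chemokine receptor Cxcr6 (3.06 ± 0.59). Ikzf2 fell by 1.24 (adjusted p = 0.00053), whereas Foxp3 was not called (-0.36 ± 0.43, adjusted p = 0.635). Among the largest falls were the nuclear long noncoding RNAs Malat1 (chr19:5795690-5802671, -2.69 ± 0.31) and Neat1 (-2.81 ± 0.38), the keratinocyte protein Lad1 (-3.19 ± 0.63), Leng8 (-2.56 ± 0.18) and Fam193b (-2.51 ± 0.23).

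Inflammatory cytokines rose in 7 of 18 cases in c-RelKO Treg (8 adjusted over the list alone), including Ifng (2.34) and Il21 (1.46), with a list adjusted p of 6.0e-08, and adjusted p = 0.168 with an estimated correlation. NK and CD8 T cell markers rose in 4 of 9 cases, such as Klrk1 and Eomes (1.05), with a list adjusted p of 7.9e-07, and adjusted p = 0.13 with an estimated correlation. Markers of other cells moved as well: MHC class II genes rose in 4 of 7 cases (Cd74 2.24, H2-Ab1 3.13; list adjusted p = 1.1e-05, and adjusted p = 0.247 with an estimated correlation). B cell markers lay higher by a median of 1.56, none of 11 called (list adjusted p = 1.8e-05, and adjusted p = 0.312 with an estimated correlation). Myeloid markers rose in 1 of 15 cases, Fcer1g (2.75), and 9 adjusted over the list alone (list adjusted p = 1.5e-06, and adjusted p = 0.25 with an estimated correlation). Erythroid markers rose in 1 of 7 cases, Car2 (2.47; list adjusted p = 0.0011, and adjusted p = 0.312 with an estimated correlation). Replicate 2 had 13300 FPKM of the hemoglobin gene Hba-a1, 78 of the B cell receptor gene Cd79a and 172 of the lysozyme gene Lyz2.

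For c-RelKO Treg 1223 genes were called, 187 higher and 1036 lower, and 4803 with the run as a block. Without replicate 1 or 2 the count was 449 or 455, and without the 3 libraries of doubtful label or purity it was 466. The WT and c-RelKO libraries differed in scale by -0.195 in log2 size factor; with size factors 404 genes were higher and 686 lower, so the share of higher genes went from 15.3% to 37.1%.

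DKO Treg fell in Foxp3 by 4.09 ± 0.43, from 259 ± 108 to 14.6 ± 9.32 FPKM (adjusted p = 1.8e-05, n = 2 and 4). Lrrc32 fell by 3.22 ± 0.72 (39.3 ± 15.9 against 461 ± 270 FPKM), Ikzf2 by 2.30, Cd83 (chr13:43880476-43898501) by 4.77 ± 0.63 and the costimulatory receptor Cd27 by 3.29 ± 0.31. The type 2 cytokines Il5 (chr11:53534296-53538605) and Il13 (chr11:53444825-53448204) rose by 7.83 ± 0.78 and 7.19 ± 0.89, to 326 ± 122 and 263 ± 50.1 FPKM. The interferon-induced membrane proteins rose, Ifitm1 by 6.91 ± 0.71, Ifitm2 (chr7:148140738-148141860) by 6.19 ± 0.18 and Ifitm3 by 5.95 ± 0.63. Further rises were those of the leukotriene receptor Cysltr1 (5.28 ± 0.37), the histamine enzyme Hdc (5.25 ± 0.56), the histamine receptor Hrh4 (46.8 ± 3.22 against 0.56 ± 0.58 FPKM) and Cxcr6 (5.15 ± 0.59). Rela was just short of the call (-0.62 ± 0.23, adjusted p = 0.0515).

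The Treg signature was split in DKO Treg: of 35 genes 10 fell, such as Foxp3, Ikzf2 and Folr4 (-2.15), 7 rose and 18 were not called (list adjusted p = 0.119). A block for the run gave 20 that fell and 11 that rose (list adjusted p = 0.0057, and adjusted p = 0.244 with an estimated correlation). Cell cycle genes rose in 23 of 24 cases, with a median of 2.85 and Mcm5 at 2.28 (list adjusted p = 1.3e-14, and adjusted p = 0.312 with an estimated correlation). Effector Treg genes rose in 13 of 29 cases and fell in 2, with Pparg at 3.31, Havcr2 at 3.12 and Tbx21 at 2.03 (list adjusted p = 0.0091, and adjusted p = 0.391 with an estimated correlation); with the run as a block 16 rose and 7 fell, and the list was not called (list adjusted p = 0.294). Markers of other cells were also higher: NK and CD8 T cell markers rose in 5 of 9 cases, such as Gzma (4.01) and Klrk1 (2.95; list adjusted p = 0.139), and MHC class II genes lay higher by a median of 0.99, with 0 of 7 called and 6 with the run as a block (list adjusted p = 0.488). Resting or central T cell genes fell in 11 of 16 cases and rose in 1, with Foxp1 at -1.61 and Foxo1 at -1.55 (list adjusted p = 4.7e-05, and adjusted p = 0.0846 with an estimated correlation). NF-kB feedback and target genes fell in 10 of 23 cases and rose in 2, with Traf1 at -1.52, Birc3 at -1.13 and Cd83 (list adjusted p = 0.0088, and adjusted p = 0.517 with an estimated correlation). TCR early response genes fell in 11 of 24 cases and rose in 2, with Egr3 at -3.16 and Zfp36 at -2.39 (list adjusted p = 0.00025, and adjusted p = 0.69 with an estimated correlation). TNF receptor superfamily genes fell in 5 of 13 cases, for example Cd27 and Fas (-2.35; list adjusted p = 0.015, and adjusted p = 0.0926 with an estimated correlation). Glycolysis genes rose in 8 of 15 cases, with Ldha at 1.62 and Tpi1 at 2.29 (list adjusted p = 0.00025, and adjusted p = 0.0878 with an estimated correlation). For DKO Treg 3803 genes were called, 2239 higher and 1564 lower, and 7062 with the run as a block; at least 2-fold were 1012 and 786 of them. Leaving out replicate 1 or 2 gave 2164 or 2120.

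**Figure D2:**
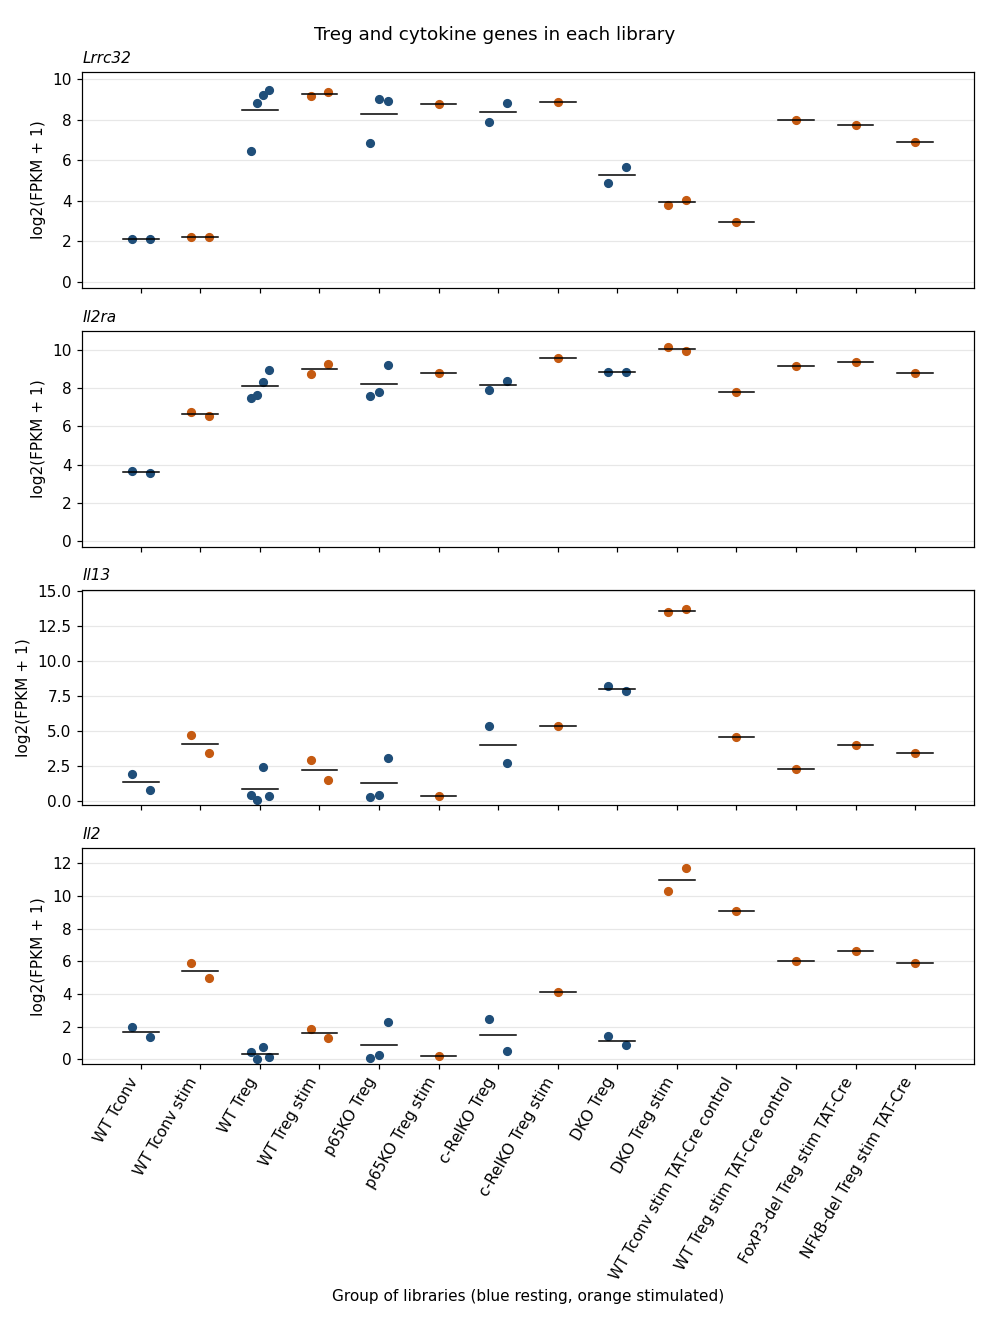
Lrrc32, Il2ra, Il13 and Il2 in each library as log2(FPKM + 1). Dots are libraries, lines are group means, blue is unstimulated and orange is stimulated.

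A broader set of genes that differed between WT Treg and WT Tconv was tested against 2 of the WT Treg libraries, and its values depended on which. This Treg program of 487 Treg-high and 415 Tconv-high genes was taken from WT Treg replicates 3 and 4 and tested against replicates 1 and 2. These controls are of runs 1 and 2, whereas all c-RelKO and DKO libraries are of runs 3 and 4, so the differences hold those between runs. In DKO Treg 133 of the Treg-high genes were lower and 112 higher, with a median of -0.10 (camera p = 0.379), and the Tconv-high genes were lower by a median of -0.46 (149 lower, 32 higher; camera p = 2.9e-06, and p = 0.4 with an estimated correlation). In c-RelKO Treg the Treg-high genes had a median of 0.17 (65 lower, 43 higher; camera p = 3.1e-06, and p = 0.148 with an estimated correlation) and the Tconv-high genes -0.53 (86 lower, 16 higher; camera p = 0.0264, and p = 0.685 with an estimated correlation). p65KO Treg had medians of 0.31 and -0.30 with 0 genes called in limma (camera p = 2.2e-11 and 2.3e-18, and p = 0.0479 and 0.131 with an estimated correlation).

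With the program taken from replicates 1 and 2 and tested against replicates 3 and 4, which share their runs with the c-RelKO and DKO libraries, it held 957 Treg-high and 263 Tconv-high genes. The Treg-high genes then turned higher in DKO Treg, with a median of 0.37 (137 lower, 353 higher; camera p = 0.0576), and the Tconv-high genes were at -0.30 (72 lower, 33 higher; camera p = 4.9e-06, and p = 0.0749 with an estimated correlation). In c-RelKO Treg they were at 0.24 (36 lower, 60 higher; camera p = 1.5e-06, and p = 0.212 with an estimated correlation) and -0.12 (20 lower, 12 higher; camera p = 0.416). In p65KO Treg the Treg-high genes were at 0.76 with 330 called higher and 4 lower (camera p = 4.7e-18, and p = 0.0374 with an estimated correlation), and the Tconv-high genes at -0.28 with 23 called lower and 2 higher (camera p = 1.8e-19, and p = 0.0028 with an estimated correlation). This list came from WT Treg of runs 1 and 2 against Tconv of runs 3 and 4, and 2 of the 3 p65KO libraries are of runs 1 and 2, so differences between runs enter both the list and the p65KO values. WT Treg replicate 1 was also high in markers of other cells. Mean log2 levels were 2.439 for B cell, 4.81 for MHC class II and 2.849 for Myeloid markers, against 0.835, 3.177 and 1.211 in replicate 2. Genes of other cells may therefore stand among the 957. The fixed Tconv signature went the other way in c-RelKO Treg than the Tconv-high genes: 2 of its 15 genes rose, Pde3b (2.45) and Cd40lg (1.65), and 7 rose and 1 fell with the run as a block (list adjusted p = 0.00046 and 0.00043, and adjusted p = 0.0931 and 0.243 with an estimated correlation).

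Direct comparison of the single knockouts put Rel 4.66 ± 0.81 higher and Rela 0.97 ± 0.24 lower in p65KO than in c-RelKO Treg (adjusted p = 0.0030 and 0.0189, n = 3 and 2). Higher in p65KO Treg were Neat1 (2.91 ± 0.41), Leng8 (2.35 ± 0.19), the inhibitory receptor gene Lilrb4 (2.55 ± 0.56) and Ikzf2 (1.43). Higher in c-RelKO Treg were Il22 (-4.41 ± 0.64), Pde3b (-3.36 ± 0.29), Klrb1b (-3.42 ± 0.24) and Cxcr6 (-2.90 ± 0.63). Markers of other cells were lower in p65KO Treg too, with medians of -1.66 for B cell markers (1 of 11 called, and 11 with the run as a block), -2.80 for MHC class II genes (3 of 7, and 6), -0.88 for NK and CD8 T cell markers (5 of 9, and 6), -1.16 for Myeloid markers (0 of 15, and 5) and -3.04 for Erythroid markers (0 of 7, and 5). Of 15 Tconv signature genes 3 were lower in p65KO Treg, Pde3b, Cd40lg (-2.17) and Satb1 (-1.62), with a median of -0.62 (list adjusted p = 1.1e-06, and adjusted p = 0.0087 with an estimated correlation). NF-kB feedback and target genes were lower in 3 of 23 cases, with Icam1 at -1.83 and Tnip1 at -1.11 (list adjusted p = 8.7e-08, and adjusted p = 0.0825 with an estimated correlation). In all 1625 genes were called, 1437 higher and 188 lower in p65KO Treg, and 4605 with the run as a block. A scale difference of 0.296 lay between these groups; with size factors 581 were higher and 368 lower (61.2% against 88.4% higher). Without c-RelKO replicate 2 the count was 419, without replicate 1 it was 455, without p65KO replicate 1 it was 665, and without the 3 doubtful libraries it was 275.

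The DKO effect went beyond the sum of the single effects for Foxp3, which lay 3.53 ± 0.63 lower than that sum (interaction -3.53, adjusted p = 0.0129). The immediate-early transcription factors Egr3 (chr14:70477252-70479964, -4.20 ± 0.59), Egr2 (-3.64 ± 0.65) and Egr1 (-3.43 ± 0.61) lay below it as well, as did Cxcr5 (-3.43 ± 0.45) and Cd27 (-3.17 ± 0.45). Above it lay Il5 (5.36 ± 1.14), the chemokine Cxcl3 (4.81 ± 0.72), Ifitm2 (3.74 ± 0.27), Hrh4 (3.70 ± 0.47) and the imprinted gene Peg10 (3.04 ± 0.18). For Egr1 part of the departure came from the single knockouts. It was 55.4, 49.8 and 178 FPKM in p65KO Treg, with 178 in replicate 3 of doubtful label, and 83.2 and 61.7 in c-RelKO Treg. WT Treg had 41.2, 59, 41.4 and 28.9 FPKM and DKO Treg 16 and 8.58. TCR early response genes were below the sum in 4 of 24 cases (10 adjusted over the list alone), with a median of -2.03 (list adjusted p = 2.2e-11, and adjusted p = 0.138 with an estimated correlation). TNF receptor superfamily genes were below it in 2 of 13 cases, Cd27 and Tnfrsf1b (-2.01; list adjusted p = 0.00063, and adjusted p = 0.0278 with an estimated correlation). Resting or central T cell genes were below it in 1 of 16 cases, Foxp1 (-1.08), and 8 adjusted over the list alone (list adjusted p = 1.5e-07, and adjusted p = 0.0195 with an estimated correlation). In all 220 genes were called, 127 above and 93 below, and 4433 with the run as a block; with size factors, for a scale difference of 0.189, 83 were above and 121 below (40.7% against 57.7% above). The count was 67 without c-RelKO replicate 2, 71 and 93 without a DKO library, 83 without p65KO replicate 2, 107 without WT Treg replicate 4, 340 without p65KO replicate 1 and 115 without the 3 doubtful libraries.

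Loss of c-Rel alone and of both subunits changed many of the same genes. 565 were lower in both, Rel, Malat1 and Lad1 among them, 92 were higher in both, such as Il13, Cxcr6 and Plac8, and 24 went in opposite directions. Independent lists would share 141 and 36.3. Simulated unchanged groups with the same controls shared 0 and 0, but few genes of unchanged groups can be called at all. That overlap is therefore no chance level for these lists. The correlation over all genes was 0.415 (0.33 simulated from the shared controls alone), and the covariance 0.215 against 0.042. These simulations leave out the runs. With run effects put in, a test chosen after the data were seen, unchanged groups again shared 0 and 0, which is uninformative for the same reason. Their correlation was 0.799, above the 0.415 observed, and their covariance was 0.105, below the 0.215 observed. The correlation without a block thus does not go beyond that of run effects alone. With the run as a block 1403 genes were lower in both, 1091 higher in both and 630 opposite (720 and 674 for independent lists), with a correlation of 0.479 (0.432 simulated) and a covariance of 0.274 (0.02 simulated). With separate controls the overlaps were 272 to 496 lower and 29 to 118 higher, the correlation 0.112 to 0.471 and the covariance 0.075 to 0.236. p65KO Treg shared 3 higher and 1 lower gene with DKO Treg, and the covariance was 0.166 (0.042 simulated; 0.028 to 0.137 with separate controls). Separate controls gave 0 to 318 higher and 0 to 36 lower for this pair. The fit with runs as a block had 687 higher in both, 178 lower in both and 48 opposite (303 higher and 48.5 lower for independent lists), with a correlation of 0.55 (0.251 simulated) and a covariance of 0.16 (0.01 simulated).

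Stimulation of WT Tconv induced Sema7a, a membrane-bound semaphorin (chr9:57787942-57810672), from 1.62 ± 0.269 to 246 ± 12.2 FPKM (6.56 ± 0.69, adjusted p = 9.1e-05, n = 2 and 2). The transcription factors Irf8 (5.57 ± 0.57), Egr1 (5.17 ± 0.49), Tbx21 (4.47 ± 0.34) and Egr3 (4.19 ± 0.47) rose, as did the cytokines Tnf (4.26 ± 0.49) and Lif (4.50 ± 0.82), the chemokine Ccl4 (5.18 ± 1.01) and the signalling inhibitor Socs1 (4.03 ± 0.49). The sphingosine phosphate receptors S1pr1 (-1.91 ± 0.40) and S1pr4 (-1.96 ± 0.43) fell, and so did Mex3b (-1.80 ± 0.27). Inflammatory cytokines rose in 9 of 18 cases (13 adjusted over the list alone), Il2 by 3.73 (list adjusted p = 9.7e-10, and adjusted p = 0.193 with an estimated correlation), and TCR early response genes in 10 of 24 (list adjusted p = 2.6e-11, and adjusted p = 0.233 with an estimated correlation). Cholesterol synthesis genes rose in 6 of 14 cases, with Sqle at 1.86 and Idi1 at 2.03 (list adjusted p = 0.00029, and adjusted p = 0.139 with an estimated correlation). Interferon response genes rose in 5 of 19 cases, with Gbp2 at 2.45 (list adjusted p = 5.6e-05, and adjusted p = 0.273 with an estimated correlation). Called were 1367 genes, 772 higher and 595 lower, and 4966 with the run as a block, where more were lower (1994 higher, 2972 lower); without any 1 of the 4 libraries 407 to 614 were called.

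WT Treg responded less. No gene was called by limma after stimulation (0, with 311 at an unadjusted p under 0.05, 0 with the run as a block and 3120 with the replicate number as a block). That number puts the stimulated libraries beside WT Treg of runs 1 and 2, so the 3120 genes hold differences between runs. The stimulated libraries are of runs 3 and 4, and WT Treg replicate 1 of run 1 was low in Foxp3, Rel and early response genes, which enters the differences: Foxp3 was at 0.39 ± 0.43 and Rel at 1.05 ± 0.77, but at -0.02 and 0.26 with the run as a block. TCR early response genes lay higher by a median of 0.89 (0.32 with the run as a block), led by Egr1 (1.54) and Egr3 (1.44), with 0 of 24 called and 2 adjusted over the list alone (list adjusted p = 2.0e-11, and adjusted p = 0.257 with an estimated correlation). The mean log2 level of this list was already 7.089 and 6.765 in unstimulated WT Treg of runs 3 and 4, against 5.463 and 5.226 in WT Tconv. After stimulation it was 7.387 and 7.225 in Treg and 7.552 and 7.453 in Tconv. Of 459 genes induced in Tconv the median in Treg was 0.28 and 0 were called (camera p = 4.4e-36, and p = 0.0035 with an estimated correlation). The response of Treg was below that of Tconv for Sema7a (-5.45 ± 0.91), Hivep3 (-4.91 ± 0.67), Il15ra (-4.34 ± 0.65), Irf8 (-4.23 ± 0.76), Tbx21 (-3.67 ± 0.45), Egr1 (-3.63 ± 0.65) and Tnf (-3.44 ± 0.66). Above it were Clcf1 (1.35 ± 0.19), Ranbp10 (1.54 ± 0.28) and the kinase Tec (1.29 ± 0.26). For this interaction 119 genes were called, 10 above and 109 below, and 1842 with the run as a block, where the sides were nearly even (889 above, 953 below); single libraries left out gave 7 to 164, with 7 without Treg stim replicate 1 and 8 without Tconv replicate 2.

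After stimulation WT Treg remained far from WT Tconv. Foxp3 was 7.58 ± 0.50 higher (adjusted p = 1.8e-06, n = 2 and 2), Lrrc32 7.06 ± 0.83, the inhibitory receptor Ctla4 4.47 ± 0.72, the integrin Itgb8 4.49 ± 0.69 and the IL-33 receptor Il1rl1 4.63 ± 0.85. Lower in Treg were Sema7a with 7.08 ± 3.26 against 246 ± 12.2 FPKM, Ly6a (-4.22 ± 0.64), Il2 (chr3:37019642-37024876) with 2.04 ± 0.857 against 43.7 ± 19.6 FPKM (-3.83 ± 0.73), and the GTPases Irgm1 (-3.37 ± 0.45) and Tgtp2 (-3.36 ± 0.37). The Treg signature was higher in 25 of 35 cases (31 adjusted over the list alone; list adjusted p = 2.0e-32, and adjusted p = 0.00027 with an estimated correlation). Inflammatory cytokines were lower in 5 of 18 cases (11 adjusted over the list alone), with Tnfsf11 at -1.91 (list adjusted p = 1.4e-06, and adjusted p = 0.236 with an estimated correlation). T cell identity genes were lower in 1 of 12 cases, Cd247 (-1.01), with a median of -0.66 (list adjusted p = 0.015, and adjusted p = 0.46 with an estimated correlation). Called were 766 genes, 418 higher and 348 lower, 4270 with the run as a block (1935 higher, 2335 lower), and 273 to 307 without any 1 of the 4 libraries.

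Stimulated DKO Treg held cytokine transcripts at levels seen in no other group. Il13 was 12400 ± 979 FPKM against 4.17 ± 3.28 in stimulated WT Treg (11.39 ± 1.03, adjusted p = 5.0e-06, n = 2 and 2). Il3 (chr11:54078587-54080781) rose by 10.90 ± 0.69, Csf2 (chr11:54060772-54063401) by 10.32 ± 0.62, Il5 by 10.32 ± 0.90, Ifng by 9.77 ± 0.72, Il4 by 9.72 ± 1.07, Il2 by 9.41 ± 0.73 and the chemokine Ccl1 by 10.15 ± 0.82. Foxp3 (-5.25 ± 0.50), Lrrc32 (-5.32 ± 0.83), Cd83 (-4.46 ± 0.73), the lymph node homing receptor Ccr7 (-4.16 ± 0.85) and the transcription factor Klf2 (-3.77 ± 0.32) fell. Of 18 Inflammatory cytokines 17 rose, with a median of 7.62 (list adjusted p = 3.4e-16, and adjusted p = 0.0445 with an estimated correlation). Cell cycle genes rose in 23 of 24 cases, Rrm2 by 3.41 (list adjusted p = 8.2e-13, and adjusted p = 0.275 with an estimated correlation). Resting or central T cell genes fell in 12 of 16 cases and rose in 1 (Bcl2 -2.45, Lef1 -1.99; list adjusted p = 8.5e-06, and adjusted p = 0.0317 with an estimated correlation). Glycolysis genes rose in 10 of 15 cases (list adjusted p = 4.1e-06, and adjusted p = 0.0317 with an estimated correlation). Called were 3774 genes, 1909 higher and 1865 lower, 7230 with the run as a block, 1903 without WT Treg stim replicate 1 and 2126 without DKO Treg stim replicate 2.

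The response to stimulation was larger in DKO than in WT Treg for Il3 (10.23 ± 0.91, adjusted p = 4.0e-05), Il2 (8.62 ± 0.96), the chemokine Ccl3 (8.62 ± 1.23), Csf2 (8.20 ± 0.82), Ifng (7.20 ± 0.95), Il21 (6.32 ± 0.58) and Il17f (6.10 ± 0.56). It was smaller for Klf2 (-2.44 ± 0.42), the cell cycle inhibitor Cdkn1b (-1.46 ± 0.32) and Ccng2 (-1.61 ± 0.28). Inflammatory cytokines responded more in 11 of 18 cases (15 adjusted over the list alone; list adjusted p = 4.3e-40, and adjusted p = 0.0049 with an estimated correlation), and TCR early response genes in 5 of 24, with Egr2 at 4.38 and Egr3 at 4.08 (list adjusted p = 2.1e-11, and adjusted p = 0.338 with an estimated correlation). For the TCR early response list the difference lay in the unstimulated cells. Its mean log2 level was 5.203 and 4.676 in DKO Treg, against 7.089 and 6.765 in WT Treg of the same runs. After stimulation it was 7.411 and 7.242 against 7.387 and 7.225. The 459 genes induced in Tconv responded more by a median of 0.53, with 34 called higher and 0 lower (camera p = 1.1e-38, and p = 0.0028 with an estimated correlation). Without stimulation these genes went both ways between DKO and WT Treg (83 higher, 70 lower; median 0.04, camera p = 0.667), and after it they were 0.63 higher (194 higher, 20 lower; camera p = 4.8e-13, and p = 0.0571 with an estimated correlation). Called were 112 genes, 85 above and 27 below, and 1612 with the run as a block, where most were below (523 above, 1089 below); a scale difference of -0.109 gave 101 and 10 with size factors (91% against 75.9% above). Leaving out single libraries gave 34 to 129, with 34 without WT Treg stim replicate 1.

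The single p65KO library labelled stimulated had more Gzmb (3.32 ± 0.62, adjusted p = 0.0382, n = 1 and 2) and Lgals3 (3.07 ± 0.56) than stimulated WT Treg. It also had more of the mitotic genes Stmn1 (2.65 ± 0.57), Aurka (2.43 ± 0.48) and Cdca5 (2.53 ± 0.52). It had less of the ubiquitin ligase Cbl (-2.48 ± 0.33), Klf7 (-1.79 ± 0.23) and the inhibitory receptor Btla (-1.37 ± 0.28). Of 24 Cell cycle genes 1 was called, Mcm6 (0.99), and 23 adjusted over the list alone (list adjusted p = 1.9e-16, and adjusted p = 0.448 with an estimated correlation). TCR early response genes lay lower by a median of -1.02, 0 called and 4 adjusted over the list alone, with Egr3 at -2.26 (list adjusted p = 3.1e-07, and adjusted p = 0.448 with an estimated correlation). The 459 genes induced in Tconv lay lower by a median of -0.24 (camera p = 7.6e-13, and p = 0.059 with an estimated correlation). Called were 117 genes, 75 higher and 42 lower, 3139 with the run as a block, and 0 or 49 without 1 of the WT libraries. With a scale difference of 0.191 taken out by size factors 106 were higher and 127 lower (45.5% against 64.1% higher).

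**Figure D3:**
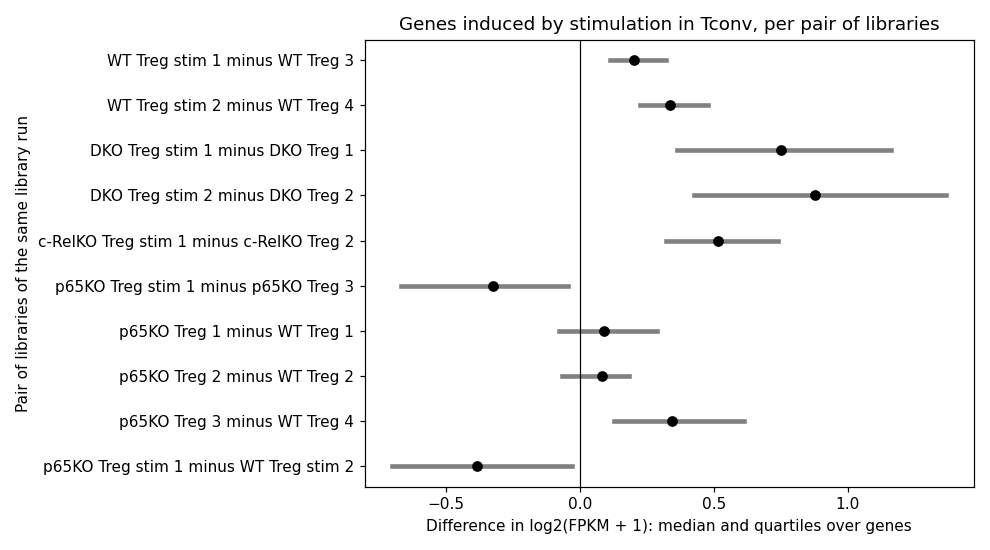
Log2 differences between single libraries of the same run over the 459 genes induced by stimulation in WT Tconv. Points are medians and bars span the quartiles.

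Pairs of single libraries from the same run showed where the p65KO libraries stood. Stimulated minus unstimulated medians over the 459 genes were 0.20 and 0.33 for WT Treg, 0.75 and 0.88 for DKO Treg and 0.52 for c-RelKO Treg. The c-RelKO value rests on c-RelKO Treg replicate 2, of doubtful purity. For p65KO Treg the library labelled stimulated lay below replicate 3 (median -0.33, Egr1 -2.56, Il2 -2.07). Replicate 3 lay above WT Treg replicate 4 (median 0.34, Egr1 2.58, Il2 2.15), whereas p65KO replicates 1 and 2 were at 0.09 and 0.08 against the WT libraries of their runs.

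In the single stimulated c-RelKO library Il17f (3.46 ± 0.52, adjusted p = 0.0167, n = 1 and 2) and Il21 (3.07 ± 0.54) were higher than in stimulated WT Treg. Rel (-6.65 ± 1.08), Malat1 (-2.34 ± 0.44), Leng8 (-2.02 ± 0.25), Clcf1 (-1.76 ± 0.18) and the GABA receptor gene Gabbr1 (-1.77 ± 0.18) were lower. Inflammatory cytokines were higher in 2 of 18 cases (6 adjusted over the list alone), with a median of 2.03 (list adjusted p = 2.3e-15, and adjusted p = 0.157 with an estimated correlation). The 459 genes induced in Tconv were higher by a median of 0.28 (3 called; camera p = 2.0e-21, and p = 0.0175 with an estimated correlation). Called by limma were 40 genes, 7 higher and 33 lower, with 799 at an unadjusted p under 0.05, 986 with the run as a block, and 2 or 8 without 1 of the WT libraries.

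The TAT-Cre libraries were compared without replicates. In the library labelled NFkB-del Il10 was 171 FPKM against 33.9 in the Treg control (2.30), Il17a was 2.46 higher, Ifng 1.66 and Lgals3 2.55, while Rel was -2.12, the survival gene Bcl2l1 -0.77 and Cd83 -0.69. At least 2-fold higher were 164 genes and 48 were lower. Effector Treg genes had a median of 0.64 with 12 of 29 at least 2-fold higher, Inflammatory cytokines 0.70, and Cell cycle genes 0.85 with 7 of 24 at least 2-fold higher, all 3 at percentile 100 of random lists. Against the library labelled FoxP3-del, the other possible control, they were at -0.42 (percentile 0), 0.11 (percentile 99.9) and -0.30 (percentile 0). Compared with the Treg control, NF-kB feedback and target genes were at -0.20 (percentile 0.1), Apoptosis regulators at -0.20 (percentile 0.59) and the TNF receptor superfamily at -0.25 (percentile 0.22). Compared with the library labelled FoxP3-del, these 3 lists were at -0.12 (percentile 1.86), -0.12 (percentile 6.1) and -0.37 (percentile 0). Erythroid and Myeloid markers were also above the Treg control, at 4.31 and 1.64, with Hba-a1 at 1110 against 46.9 FPKM.

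In the library labelled FoxP3-del, whose Foxp3 was 1.61 higher than in the control, Gzmb was 43.1 against 6.04 FPKM (2.65), the inhibitory receptors Havcr2 and Klrg1 were 2.08 and 1.96 higher, and Egr3 and Nr4a3, targets of receptor signalling, were at -1.23 and -1.15. At least 2-fold higher were 305 genes and 25 were lower. Effector Treg genes had a median of 1.02 with 15 of 29 at least 2-fold higher, Cell cycle genes 1.29 with 16 of 24, and TCR early response genes -0.34 (percentile 0). Markers of other cells were higher as well, Myeloid markers by a median of 1.45 with 6 of 9 at least 2-fold higher, B cell markers by 0.80 and MHC class II genes by 0.64. NF-kB feedback and target genes were at 0.03 (percentile 81.3). Between the Treg and Tconv controls Lrrc32 was 5.06 and Ikzf2 3.67 higher in Treg, Il2 was 63.5 against 534 FPKM (-3.05), and 14 of 16 Inflammatory cytokines were at least 2-fold lower; 1272 genes were at least 2-fold higher and 170 lower, with a scale difference of 0.248. Markers of other cells were higher in the Treg than in the Tconv control too. B cell markers had a median of 1.57 with 8 of 9 at least 2-fold higher, MHC class II genes 1.23 with 5 of 7, and Erythroid markers 1.56. NFkB-del against the library labelled FoxP3-del gave 46 higher and 100 lower, with TCR early response genes at 0.40.

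Genes changed at least 4-fold in stimulated DKO Treg were followed into the TAT-Cre set. The 293 risen genes had a median of 0.71 in the library labelled NFkB-del, 87.7% of them higher than in the control, and 0.86 in the library labelled FoxP3-del, 85% higher. Random gene sets of like level had 50.6% and 61.7% higher, and the medians were at percentile 100. The 220 fallen genes were at -0.07 and -0.01 (percentile 0.08 each). Both values share the same single control library. In NFkB-del against the library labelled FoxP3-del, compared after the data were seen, the 293 genes were at -0.23 (32.8% higher, 33.9% in random sets, percentile 0) and the 220 at -0.02 (percentile 100), so the sign for the 293 depends on the control.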

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

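For the p65KO libraries the tests on induced genes and on depth were chosen only after the result was seen, and the test on lowered genes was written before its value but after the pattern. Genes induced by stimulation in Tconv lay lower in the p65KO library labelled stimulated than in p65KO Treg replicate 3 of the same run, with a median of -0.327 over 459 genes, and replicate 3 stood 0.344 above WT Treg replicate 4. These values are the pattern itself and test no cause. Over the 230 genes lowered at least 2-fold by stimulation in Tconv, an exchange of the 2 labels predicts a median above 0. The WT, c-RelKO and DKO pairs of that run were at -0.305, -0.399 and -1.139. The c-RelKO pair holds c-RelKO Treg replicate 2, of doubtful purity. For the p65KO pair the median was 0.229. Any reason for replicate 3 to be the more activated library would give the same sign, so this value cannot single out an exchange. Exchanged labels may be the cause, and a real response to loss of p65 remains open. No second stimulated p65KO library exists to test it. A difference in depth between the 2 libraries is unlikely, since the ratio of implied fragments was 1.02.

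The tests on the library labelled FoxP3-del were chosen only after its Foxp3 value was seen. Foxp3 was 266 FPKM in it and 86.7 in the Treg control, and the other Treg signature genes were lower in the control by a median of -0.392, as exchanged labels would give. The signature also lay 0.172 higher in the library labelled NFkB-del than in the control, although its Foxp3 was 53.4 FPKM, so a low signature in the control is not particular to an exchange, which may be the cause but stays open. Tconv cells mixed into the control may be set aside: Foxp3 would need 68.1% of them, and the median over 41 Tconv-high genes was 3.83%. A transcript that persists, or rises, after a deletion that leaves most exons in place could give the same values, and gene-level FPKM leaves this open.

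For the loss of Foxp3 and Lrrc32 in DKO Treg the test on resting Tconv was written before its result was seen, and the test on scaling after. Resting Tconv mixed into the DKO libraries are an unlikely cause: Foxp3 would need 97.2% and 92.1% of them, whereas the medians over 42 Tconv-high genes were -3.86% and -4.08%. Of 129 Treg-high genes 121 and 125 stayed above their Tconv level, although the medians stood 42.5% and 54.7% of the way to it. Scaling is an unlikely cause too, because Foxp3 was at -4.175 with size factors. Activated or effector T cells of another kind in the sorted cells could give both the low Foxp3 and the high Il5 and Il13, as could an effect of the lost subunits on Foxp3 itself, and the libraries at hand leave both open.

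For the number of genes called in p65KO Treg the test on all regroupings was written before its result was seen, and the one within runs was chosen after. Of 35 splits of these 7 libraries into 3 and 4, 8 called at least as many genes as the real one, which called 5, so for the count without a block chance cannot be excluded by these splits, which leave the run aside. The highest other split called 3704. It put WT Treg replicates 3 and 4 with p65KO replicate 3, the libraries of the later 2 runs, so it points to a structure of the samples that follows the runs. With the run as a block 1017 genes were called, and 119 without the doubtful libraries. Exchanging p65KO and WT Treg only within runs 1, 2 and 4, with the run as a block, gives 8 splits, too few for a share under 0.05; the highest other split called 0.

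Among 26 gene lists and genes compared between the 4 WT Treg libraries, 5 had 1 library apart by Dixon's test on the gap over the range at 0.05, where chance sets apart about 1 in 20 such groups. Replicate 1 was low for the Treg signature (0.89; 5.96 against 6.75 to 6.84 in mean log2 units), NF-kB feedback and target genes (0.88), TCR early response (0.865) and Rel (0.864). Replicate 4 stood apart in the Sex check genes (0.909), and it had Y-linked transcripts that the other 3 lacked. The response to stimulation differed between Treg and Tconv in 119 genes and between DKO and WT Treg in 112, and 220 genes departed from the sum of the single knockouts. These 3 counts come from tests fixed before the data were examined.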

How the results depend on the processing

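The alternatives without 3 libraries and the overlaps of knockouts with the run as a block were chosen only after the data were seen; the others were fixed before. Counts of called genes moved widely with a block, with a fit on the compared groups only and with single libraries left out, and the cause was not tested. Named-gene results include list members whether called or not. They count as the same where neither fit called the gene, whatever its direction, so these numbers do not measure how stable large changes are. With the run as a block 1110 named-gene results stayed the same and 333 became stronger. With 1 library left out 7510 stayed, 129 became stronger and 895 weaker. With a pseudocount of 0.1 the numbers were 1395 the same, 5 stronger and 43 weaker, without the filter 1381 and 62 weaker, with size factors 1389, 26 stronger and 28 weaker, and with the compared groups only 1008, 34 stronger and 186 weaker. Without the 3 doubtful libraries 1223 stayed, 21 became stronger and 86 weaker, and with the run as a block added 1033 stayed, 281 became stronger and 16 weaker.

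With the library run as a block the counts were 5287 for WT Treg vs WT Tconv (1449 without a block), 1017 for p65KO Treg (5), 4803 for c-RelKO Treg (1223), 7062 for DKO Treg (3803), 4605 for p65KO vs c-RelKO Treg (1625), 4433 for the departure of DKO from additivity (220), 0 for WT Treg stim, 4966 for WT Tconv stim (1367), 1842 for stimulation by cell type (119), 4270 for WT Treg stim vs WT Tconv stim (766), 7230 for DKO Treg stim (3774), 1612 for stimulation by DKO (112), 3139 for p65KO Treg stim (117) and 986 for c-RelKO Treg stim (40).

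Replicate numbers did not pair WT Treg with stimulated WT Treg. WT Treg replicates 1 and 2 are of runs 1 and 2, and WT Treg stim replicates 1 and 2 of runs 3 and 4. The Y-linked gene Ddx3y was 0 FPKM in WT Treg replicate 2 and 108 in WT Treg stim replicate 2. In the groups with replicates 1 and 2 of runs 3 and 4, number and run cannot be told apart. Of 19 libraries 17 correlated best with one of their own number and 18 with one of their own run. Deviations from group means correlated by 0.222 on average between libraries with the same number (lowest -0.499, 57 pairs) and by -0.127 with different numbers (99 pairs). The negative value partly follows from the positive one, because deviations in groups of 2 libraries mirror each other. Taken as a block, the replicate number gave 3052 genes for WT Treg vs WT Tconv, 3268 for c-RelKO Treg, 4217 for p65KO vs c-RelKO Treg, 585 for the departure from additivity, 3120 for WT Treg stim, 2403 for WT Tconv stim, 1221 for stimulation by cell type, 1698 for WT Treg stim vs WT Tconv stim and 992 for stimulation by DKO. Of the named-gene results 1047 stayed with this block, 165 became stronger and 16 weaker. Its 3120 genes for WT Treg stim hold differences between runs.

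A fit on the compared groups only called 338 genes for WT Treg vs WT Tconv, 0 for p65KO Treg, 71 for c-RelKO Treg, 1724 for DKO Treg, 1 for p65KO vs c-RelKO Treg, 20 for the departure from additivity, 3795 for WT Tconv stim, 38 for stimulation by cell type, 2284 for WT Treg stim vs WT Tconv stim and 42 for stimulation by DKO. A pseudocount of 0.1 called 0 for p65KO Treg, 66 for stimulation by DKO and 48 for p65KO Treg stim. Without the filter 3 were called for p65KO Treg, 334 for the departure from additivity, 205 for stimulation by DKO, 191 for p65KO Treg stim and 88 for c-RelKO Treg stim. Size factors called 0 for p65KO Treg, 949 for p65KO vs c-RelKO Treg and 233 for p65KO Treg stim.

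Without p65KO Treg replicate 3, p65KO Treg stim and c-RelKO Treg replicate 2 the counts were 1413 for WT Treg vs WT Tconv, 0 for p65KO Treg, 466 for c-RelKO Treg, 3816 for DKO Treg, 275 for p65KO vs c-RelKO Treg, 115 for the departure from additivity, 0 for WT Treg stim, 1317 for WT Tconv stim, 98 for stimulation by cell type, 780 for WT Treg stim vs WT Tconv stim, 3763 for DKO Treg stim, 103 for stimulation by DKO and 26 for c-RelKO Treg stim. With the run as a block added they were 5910, 119, 4739, 7477, 3026, 3951, 1, 5667, 2437, 5009, 7712, 2247 and 1418 in the same order.

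Leaving out 1 library at a time gave 362 to 2311 genes for WT Treg vs WT Tconv, 0 to 21 for p65KO Treg, 449 to 1254 for c-RelKO Treg, 2120 to 4635 for DKO Treg, 419 to 2300 for p65KO vs c-RelKO Treg and 67 to 340 for the departure from additivity. It gave 0 to 0 for WT Treg stim, 407 to 614 for WT Tconv stim, 7 to 164 for stimulation by cell type, 273 to 307 for WT Treg stim vs WT Tconv stim, 1903 to 2804 for DKO Treg stim, 34 to 129 for stimulation by DKO, 0 to 49 for p65KO Treg stim and 2 to 8 for c-RelKO Treg stim.

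Of the gene list tests 13 were called with an estimated correlation, 128 with the preset one, 135 with the run as a block, 116 of 276 with the replicate block and 128 of 299 without the doubtful libraries. With the WT Treg replicates that define the program and serve as control swapped, the Tconv-high genes in c-RelKO Treg had a median of -0.124 and lost their call, the Treg-high genes in p65KO Treg were at 0.757, and the Treg-high genes in DKO Treg were at 0.367, above 0. With split controls p65KO and DKO Treg shared 59 genes on average and c-RelKO and DKO Treg 424. With the run as a block p65KO and c-RelKO Treg shared 346 genes in the same direction (263 higher, 83 lower) with 112 opposite. Independent lists would share 129 higher and 52 lower. Simulated unchanged groups shared 0 and 0, which is no chance level because few of their genes can be called. The covariance between p65KO and c-RelKO effects, 0.043, was above the simulated 0.01, and the correlation of 0.221 was below the simulated 0.262. p65KO and DKO Treg shared 865 with 48 opposite (0.55 against 0.251), and c-RelKO and DKO Treg 2494 with 630 opposite (0.479 against 0.432). In the TAT-Cre set the Treg signature had medians of 0.177 for NFkB-del vs control, 0.424 for the library labelled FoxP3-del vs control, 2.397 for Treg vs Tconv control and -0.378 for NFkB-del vs the library labelled FoxP3-del with a pseudocount of 0.1, and 0.178, 0.355, 1.845 and -0.304 with size factors. NF-kB feedback and target genes in the library labelled FoxP3-del turned to -0.023 with size factors.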

Other observations

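All comparisons in this part were chosen only after the values were seen. The nuclear noncoding RNA Malat1 was 205 to 354 FPKM in WT Treg, 35.3, 42 and 54.8 in the c-RelKO libraries and 19.9 to 26.3 in the DKO libraries. Leng8, a nuclear protein with a domain of mRNA export factors, followed it with 12.3 to 20.2 FPKM in c-RelKO and DKO Treg against 70.2 to 86.7 in WT Treg. In the TAT-Cre set Malat1 was 82.6 to 140 FPKM and Leng8 31.9 to 42.5, the Tconv control included. The noncoding RNA Neat1 was 25.6 FPKM in the Tconv control and 48.8 in the Treg control of that set, near the 13.1 to 36.9 of the c-RelKO and DKO libraries, against 98 to 228 in WT Treg, so low Neat1 was not limited to cells without c-Rel. For Malat1 and Leng8, each c-RelKO and DKO library was below each WT library of its run. With the run as a block Malat1 stayed at -2.67 in c-RelKO and -3.44 in DKO Treg. In p65KO Treg it was 92.6, 240 and 178 FPKM, and 94.9 in the library labelled stimulated.

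Sex differed between libraries. Xist, expressed from the inactive X chromosome of females, was 40.3 FPKM in the TAT-Cre Treg control and 1.7e-09 in the library labelled NFkB-del. Within runs, p65KO Treg replicate 1 had 0.108 FPKM of Xist against 131 in WT Treg replicate 1, and DKO Treg replicate 2 had 36.4 against 0.0075 in WT Treg replicate 4. In c-RelKO Treg replicate 2 Xist was 7.18 FPKM along with 36.5 of the Y-linked gene Ddx3y. WT Treg replicate 1 held 14.6 FPKM of Cd79a and 49 of Lyz2, genes of B cells and myeloid cells.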
